A study of Mus musculus with 10 samples.

How the data were processed

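RNA was measured in 10 frozen melanomas of C57BL6 mice carrying BrafV600E and Cdk4R24C alleles, 5 labelled pigmented and 5 labelled MPNST-like. Per the labels, the skin was treated with tamoxifen for 4 days, which switches on the mutant Braf allele, and the carcinogen DMBA was then given once on the skin. RNA was extracted with TRI Reagent and RNeasy columns, and 100 ng was turned into biotinylated cRNA. Each sample was hybridized to 1 array of the single-colour Illumina MouseWG-6 v2.0 BeadChip, with 45281 probes. The arrays sat on 2 chips that both held both groups: pigmented 1 and 2 and MPNST-like 1 and 2 on chip 1, and the other tumors on chip 2. Replicate numbers are names only and pair no tumors.

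The deposited scanner table gives, per the file headers, a mean bead intensity and a detection p-value for each probe and array. No value was negative, so no global background had been subtracted, and array medians differed, so the arrays had not been scaled to a common median. The scanner software and any local background step are not given in the sources used here. A second deposited table holds values normalized by the authors, on a log2 scale by comparison with the intensities: 2 to the power of each value was a straight line of the same array's intensity (R squared of 1 on every array). The slope of that line ran from 1.11 to 2.62 in pigmented and from 0.578 to 1.10 in MPNST-like arrays. The medians of the authors' columns were 4.79, 4.92, 5.00, 4.86 and 4.96 for pigmented 1 to 5 and 4.79, 4.85, 4.80, 4.80 and 4.82 for MPNST-like 1 to 5. The authors' normalization method remains unknown, and these values served only as an alternative.

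Intensities were processed with limma 3.58.1 in R 4.3.3. Background was corrected with neqc, a normexp model whose background comes from the detection p-values, with an offset of 16, followed by quantile normalization and log2. Probes were kept when detected at a p-value under 0.05 on at least 3 of the 10 arrays (22480 probes). Of all probes, 34885 had 1 gene symbol, 18 had several and 10378 had none. Symbols were checked against RefSeq genes of assembly GRCm38.p6 through Entrez identifiers for 34807 probes, and 0 symbols changed. The brightest probe stood for each symbol, which left 11984 genes. For 4740 genes with several detected probes, 25 had probes that passed in opposite directions. Of 3394 kept probes without a symbol, which were tested apart, 492 were higher and 469 lower.

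The number of arrays limits the precision. Median intensity ranged from 79.4 to 89.0 in pigmented and from 87.4 to 93.9 in MPNST-like arrays. Detected probes numbered 17908 to 20120 in pigmented and 19274 to 21581 in MPNST-like arrays (exact permutation p = 0.032). The 20 brightest probes held 5.12% to 6.75% of the signal above background in pigmented and 3.86% to 4.47% in MPNST-like arrays (exact permutation p = 0.0079). Of the changed genes, 132 were detected in no pigmented tumor and 26 in no MPNST-like tumor. The fold of such a gene, and of one detected in few tumors of a group, is limited by background. Correlations between arrays were 0.919 to 0.971 within pigmented, 0.897 to 0.960 within MPNST-like and 0.782 to 0.922 between the groups.

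The groups were compared with limma's lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method. Log2 differences are MPNST-like minus pigmented. Of 36 gene lists written before the data were examined, 35 had at least 4 measured genes. The cartilage and bone list had 3 and was not tested. Lists were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. List scores were compared by a two-sided exact permutation test over all 252 assignments of the tumors, adjusted over the lists. For single tumors, the deviation of a gene is its value minus the mean of the other tumors of the group, centred on the tumor's median, and 11954 genes had a chromosome in that assembly. Gene density is the number of genes within 1 Mb on each side, or per Mb of a chromosome. Chromosome medians were set against random gene lists of the same size and like expression. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

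Genes were named by a rule written before the data were examined. It takes fixed markers (Tyr, Tyrp1, Dct, Pmel, Mlana, Mitf, Sox10, Ngfr, S100b, Kit, Mcpt4, Cpa3, Braf, Cdk4 and sex-linked genes). It adds the 8 higher and 8 lower genes with the largest differences among those that passed with groups that did not overlap. From each list it takes up to 4 members that passed with the largest differences, or the largest 2 where none passed. The text names some of the genes this rule gives.

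Alternatives tried were other background corrections, median scaling, cyclic loess, the authors' values, no filter, a filter at a detection p-value under 0.01 on at least 5 arrays, the mean of a gene's probes, chip as a block, each chip alone, other variance models, stricter thresholds and leaving out each tumor in turn. The estimated correlation and fry were alternatives for the lists. A fit without 3 tumors with muscle RNA and a fit with the keratinocyte score were added after the data were seen. The steps were tested on simulated data of the same size with 12125 genes tested. Among genes changed by a log2 value of 1 up and down, 40.0% and 44.2% were called in the right direction, and among those changed by 2 up and down, 90.0% and 73.8%. Of 121 calls 4.96% fell on unchanged genes, and 0 calls were made when no gene was changed. Genes that were weak or narrowly different could thus be missed. Noise was drawn for each probe on its own. The tested genes changed by 1 up and down numbered 50 and 43, and those changed by 2 up and down 50 and 42. In the tumors 38.8% of genes differed, and genes of a list vary together. The simulated rates therefore need not hold for the real comparison.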

Results

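The MPNST-like melanomas held far less RNA of melanin synthesis genes than the pigmented melanomas, and more RNA of single genes known from nerve sheath, connective tissue and macrophages. Pmel, which forms the fibrils on which melanin is laid down, was 174-fold lower in the MPNST-like tumors (log2 difference -7.44, SE 1.12, adjusted p = 5.6e-04, n = 5 per group). Ngfr, a receptor of neural crest and immature Schwann cells, was 17.7-fold higher (4.15, SE 0.78, adjusted p = 0.0019). The matrix glycoprotein gene Tnc was 34.1-fold higher (5.09, SE 0.57, adjusted p = 1.0e-04). Aif1, expressed by macrophages, was 8.45-fold higher (3.08, SE 0.38, adjusted p = 1.8e-04). All 5 MPNST-like tumors lay beyond all 5 pigmented tumors for each of these 4 genes. The sizes moved with the processing. Over 25 alternatives the log2 difference ran from -9.69 to -5.94 for Pmel, 3.19 to 5.12 for Ngfr, 2.54 to 6.32 for Tnc and 1.97 to 3.75 for Aif1.

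The comparison addressed how amelanotic tumors that resemble malignant peripheral nerve sheath tumors (MPNST) differ from pigmented melanomas of the same mouse model. Of 11984 genes tested, 2228 were higher and 2418 were lower in the MPNST-like tumors at an adjusted p under 0.05, of which 1267 and 1054 differed by a log2 value of at least 1. The groups did not overlap for 3099 genes (25.9%), where chance gives 0.794%. The largest non-overlapping increases were in Actg2 (5.54), a smooth muscle actin, the protocadherin Pcdh20 (5.46), Reln (5.32), which encodes the matrix protein reelin, and the growth cone gene Gap43 (5.14). Their lowest values over 25 alternatives were 4.51 for Actg2, 3.95 for Pcdh20, 2.66 for Reln and 3.51 for Gap43. The largest decreases after Pmel were in the pigment cell transporter genes Slc45a2 (-6.89) and Oca2 (-6.52), and in Tspan10 (-6.69). Where a gene was near background in most tumors of a group, the size of its difference is limited by the background, as for Tspan10, detected in 2 of 5 MPNST-like tumors, and Gap43, detected in 2 of 5 pigmented tumors. The first principal component carried 56.0% of the variance and separated the groups, from -73.7 to -22.1 in pigmented tumors and from 38.8 to 63.1 in MPNST-like tumors (exact permutation p = 0.0079, the smallest that 5 against 5 tumors can give). The balance of increases and decreases moved with the scaling of the arrays. The median log2 difference of all genes was 0.011 after quantile normalization, 0.33 after median scaling (3845 higher, 902 lower) and -0.22 in the authors' values (1220 higher, 3820 lower), and the changes given here are relative to the quantile median. With chip as a block 2240 genes were higher and 2401 lower. Within chip 1 the counts were 255 and 135, within chip 2 they were 1593 and 1783, and 0 of the called genes had the other sign within either chip.

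**Figure D1:**
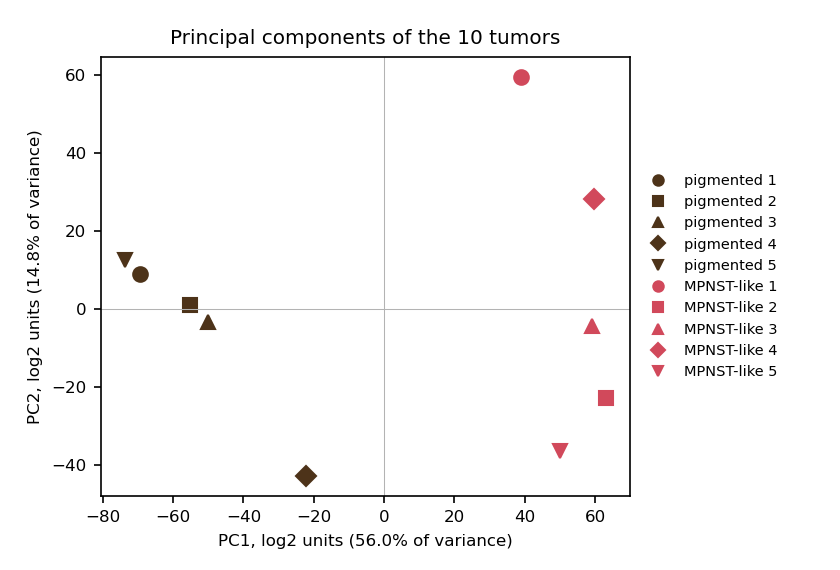
Scores of the 10 tumors on the first principal component (56.0% of the variance, horizontal axis) and the second (14.8%, vertical axis), in log2 units, with 1 point per tumor. The pigmented tumors lie between -73.7 and -22.1 on the horizontal axis and the MPNST-like tumors between 38.8 and 63.1.

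Of 35 gene lists tested with a preset correlation between genes, 12 were higher and 4 lower in the MPNST-like tumors. With an estimated correlation camera called 0 lists (6 had an unadjusted p under 0.05, and the lowest adjusted p was 0.27), while the rotation test fry called 17 higher and 5 lower. Among 100 splits of the 10 tumors into 5 and 5, the real one included, 22 gave at least 16 lists, so the number of lists is no evidence by itself. Each list is therefore given with its score per tumor, the mean log2 level of its measured members around each gene's mean, and an exact permutation p.

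Pigment genes fell as a group. Of 17 measured melanocyte pigmentation genes, 16 fell and 0 rose, both over all genes and adjusted over the list alone (camera adjusted p = 3.7e-11). The adjusted p was 0.27 with an estimated correlation. The list score differed by -4.65 (exact p = 0.0079, adjusted 0.028), by -5.86 within chip 1 and by -3.85 within chip 2. Tyr, the rate-limiting enzyme of melanin synthesis, fell by 4.31 (SE 0.40) and was detected in 1 of 5 MPNST-like tumors. Its log2 difference ran from -4.99 to -2.61 over 25 alternatives. The partner enzymes Tyrp1 and Dct fell by 6.36 (SE 1.26) and 4.59 (SE 1.35). Mlana, a melanosome protein gene, fell by 5.90 (SE 0.89). The loss was uneven between MPNST-like tumors. The pigmentation score lay between 2.10 and 2.49 in the pigmented tumors, at -3.73 in MPNST-like 1 and at -0.37 in MPNST-like 5, and Dct overlapped between the groups. Mitf, the master transcription factor of melanocytes, fell by 2.57 (SE 0.35, adjusted p = 2.8e-04) and was detected in 1 of 5 MPNST-like tumors. Melanosome biogenesis genes fell in 14 of 20 cases and rose in 2 (14 and 3 adjusted over the list alone; camera adjusted p = 5.0e-04, adjusted p = 0.27 with an estimated correlation). Their score differed by -0.70 (exact p = 0.0079), by -0.64 within chip 1 and by -0.74 within chip 2, but its size followed the scaling, at -0.27 after median scaling and -1.13 in the authors' values. Examples are the lysosomal protease gene Ctsd (-1.98), the vesicle adaptor gene Ap3d1 (-1.54) and the tetraspanin gene Cd63 (-1.33).

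**Figure D2:**
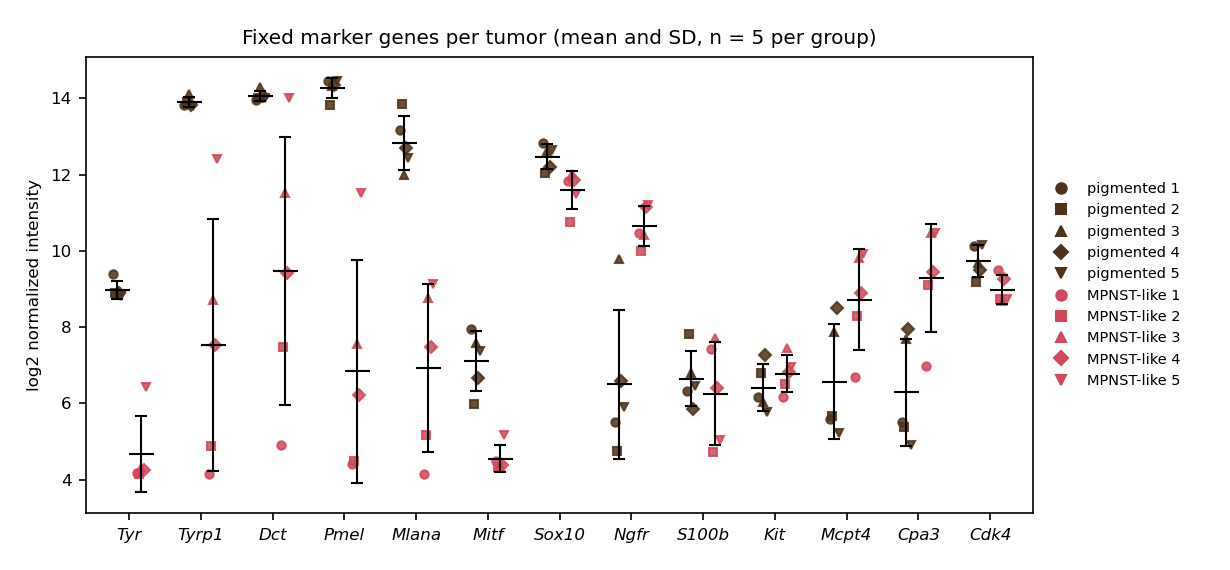
Log2 normalized intensity (vertical axis) of marker genes fixed before the data were examined, with 1 point per tumor and bars for the mean and SD of 5 tumors per group. Pmel averaged 14.28 in pigmented and 6.84 in MPNST-like tumors, Ngfr 6.50 and 10.65.

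Schwann cell and neuronal genes were higher. Of 20 Schwann cell genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.0078, adjusted p = 0.50 with an estimated correlation). The Schwann score differed by 1.20 (exact p = 0.0079), by 1.34 within chip 1 and by 1.11 within chip 2, and its difference beyond that of the endothelial score was 0.42 (exact p = 0.34). Gap43 and Ngfr led the list, followed by Egr2 (2.92), a transcription factor of myelinating Schwann cells. The glial gene S100b did not pass (-0.39, SE 0.60, adjusted p = 0.63, and 0.14 after median scaling). Sox10, needed in both melanocytes and Schwann cells, fell by 0.87 (SE 0.25, adjusted p = 0.020) from a mean log2 intensity of 12.47 to 11.60 and was detected in all 5 tumors of each group. That call ended after median scaling (-0.63, adjusted p = 0.085), within chip 1 (-1.13, 0.30) and chip 2 (-0.69, 0.056), without the tumors with muscle RNA (-0.62, 0.071) and with the keratinocyte score as a covariate (-0.65, 0.13). Of 8 neuronal genes 3 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.012, adjusted p = 0.27 with an estimated correlation). These were Gap43, which also belongs to the Schwann list, the neurofilament gene Nefm (3.99, detected in 1 of 5 pigmented tumors) and the microtubule protein gene Map2 (2.84). The neuronal score differed by 1.88 (exact p = 0.0079), by 2.22 within chip 1 and by 1.66 within chip 2, and by 1.16 without background correction. Over 22 alternatives it ran from 0.94 to 2.45. The 16 melanocyte and neural crest factors went both ways, with 5 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.91). Pax3 fell by 2.31 and Zic1 (2.32) and Snai1 (2.03) rose. Their median log2 difference was -0.10 and their score difference 0.06, with 0.45 (exact p = 0.040) after median scaling and -0.34 (exact p = 0.18) in the authors' values.

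Connective tissue genes had the largest rise of any list. Of 19 fibroblast and collagen matrix genes 18 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.0e-09, adjusted p = 0.27 with an estimated correlation). The score differed by 3.08 (exact p = 0.0079), by 3.54 within chip 1 and by 2.77 within chip 2. It ranged from 1.40 to 1.65 in MPNST-like tumors and from -2.33 to -0.21 in pigmented ones. Lum (5.09), Col3a1 (4.35) and Postn (3.91), which encode collagen fibril and matrix proteins, rose with Tnc. The dedifferentiated melanoma list, genes known from melanoma cells with little pigment, rose in 12 of 18 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 3.5e-04, adjusted p = 0.27 with an estimated correlation). Its score differed by 1.41 (exact p = 0.0079), by 1.78 within chip 1 and by 1.16 within chip 2. Besides Ngfr, the matrix protein gene Tgfbi (3.35) and the receptor kinase genes Axl (2.65) and Egfr (2.51) rose. Pericyte and smooth muscle genes rose in 7 of 12 cases and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.49 with an estimated correlation). Pdgfrb rose by 2.07, and Cspg4, which melanoma cells also express, fell by 1.73. That score differed by 0.86 (exact p = 0.016), by 1.05 within chip 1 and by 0.73 within chip 2, and by 0.51 both without background correction (exact p = 0.016) and in the authors' values (exact p = 0.095). Of 15 endothelial genes 5 rose and 1 fell, also adjusted over the list alone, with Emcn at 2.25 and Cdh5 at 1.19 (camera adjusted p = 0.016, adjusted p = 0.58 with an estimated correlation). The endothelial call ended without pigmented 2 (adjusted p = 0.050) and within chip 2 (0.22). The endothelial score differed by 0.78 (exact p = 0.048, adjusted 0.076), by 1.32 within chip 1 and by 0.42 within chip 2, and by 0.36 (exact p = 0.27) in the authors' values.

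Of 18 macrophage and monocyte genes 15 rose and 0 fell (17 and 0 adjusted over the list alone; camera adjusted p = 5.6e-05, adjusted p = 0.50 with an estimated correlation). The macrophage score differed by 1.73 (exact p = 0.016), by 2.13 within chip 1 and by 1.47 within chip 2, and the mannose receptor gene Mrc1 (2.90) rose beside Aif1. Of 11 mast cell genes 6 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.58 with an estimated correlation), among them the chymase gene Cma1 (2.85), the IgE receptor gene Fcer1a (2.43) and the protease gene Cpa3 (3.01, SE 0.77). Mcpt4 was at 2.15 (SE 0.77, adjusted p = 0.046), and its adjusted p was 0.064 to 0.11 when pigmented 1, 2 or 5 or MPNST-like 2, 3, 4 or 5 was left out. The Mcpt4 call was lost in 16 of 25 alternatives, over which its log2 difference ran from 0.87 to 2.66 (adjusted p up to 0.36). The mast cell score differed by 1.52 (exact p = 0.024), by 1.21 within chip 1 and by 1.73 within chip 2, and by 0.89 without background correction. Kit, which both mast cells and melanocytes express, did not pass (0.37, SE 0.32, adjusted p = 0.38). Of 22 chemokines and cytokines 10 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0017, adjusted p = 0.49 with an estimated correlation). The chemoattractant genes Ccl8 (4.10), Ccl11 (3.61) and Ccl7 (2.49) and the alarmin gene Il33 (3.23) rose. That score differed by 1.32 (exact p = 0.0079), by 1.52 within chip 1 and by 1.19 within chip 2, and by 0.84 without background correction. Antigen presentation genes of MHC class II rose in 7 of 11 cases and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.016, adjusted p = 0.58 with an estimated correlation), with H2-Aa at 2.29 and H2-Eb1 at 2.26. Their score differed by 1.18 (exact p = 0.032, adjusted 0.056), by 1.15 within chip 1 and by 1.21 within chip 2, and by 0.79 (exact p = 0.14) in the authors' values. Dendritic cell genes rose in 3 of 9 cases and fell in 0 (2 and 0 adjusted over the list alone), with Batf3 at 1.28 (camera adjusted p = 0.037, adjusted p = 0.49 with an estimated correlation). That camera call ended without pigmented 1 (0.063), pigmented 2 (0.050) or MPNST-like 5 (0.061). Its score differed by 0.57 (exact p = 0.016), by 0.48 within chip 1 and by 0.64 within chip 2, and by 0.46 (exact p = 0.095) in the authors' values. It was 0.29 with normexp by maximum likelihood and 0.23 without background correction (exact p = 0.016 for each). The dendritic call was lost in 11 of 27 alternatives. Beyond the endothelial score, the difference was -0.21 for dendritic (exact p = 0.48), 0.41 for MHC class II (0.28), 0.54 for chemokine (0.056) and 0.08 for pericyte genes (0.67). It was 2.30 for fibroblast (exact p = 0.0079), 1.10 for neuronal (0.016) and 0.63 for dedifferentiated genes (0.048). T cell genes did not move together, with 0 of 11 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.88; score difference 0.12, exact p = 0.54, and -0.04 in the authors' values). Foxp3 fell by 0.94, and Cd8b1 by 0.56, although Cd8b1 stood at 0.03 when all of its probes were averaged.

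Markers of skin also differed between tumors, beside these immune and vessel genes. The keratinocyte score was 1.20 to 1.35 in 4 MPNST-like tumors, -1.57 in MPNST-like 1 and 0.98 in pigmented 4, and its group difference of 1.41 had an exact p of 0.10 (0.68 within chip 1 and 1.90 within chip 2). Of 15 keratinocyte genes 3 rose and 0 fell over all genes, and 0 passed when adjusted over the list alone (camera adjusted p = 0.016, adjusted p = 0.62 with an estimated correlation). Without MPNST-like 1 the keratinocyte difference was 1.98 (exact p = 0.016), and without pigmented 4 it was 1.83 (exact p = 0.040). With the keratinocyte score as a covariate, chosen after seeing the data, 1489 genes were higher and 1494 lower, and 6 lists were higher. The mast cell (adjusted p = 0.13), endothelial (0.13), MHC class II (0.16), dendritic (0.25) and pericyte (0.059) calls of camera ended, whereas the macrophage (0.0022), fibroblast (5.5e-10), Schwann (0.0027) and pigmentation (1.0e-14) calls held. The score differences left with that covariate were 0.73 for mast cell (permutation p = 0.048), 0.53 for pericyte (0.048), 0.28 for dendritic (0.032), 0.52 for endothelial (0.17) and 0.59 for MHC class II genes (0.18). Skeletal muscle genes were high in pigmented 4 (score 3.44), MPNST-like 2 (3.75) and MPNST-like 5 (4.00) and did not follow the groups, with 0 of 13 genes passing (exact p = 1). Without these 3 tumors, a choice made after seeing the data, 1705 genes were higher and 1703 lower. The erythrocyte list was not called, with 2 of 5 genes lower over all genes and 5 of 5 adjusted over the list alone (camera adjusted p = 0.076, adjusted p = 0.58 with an estimated correlation). Its score differed by -2.02 (exact p = 0.024, and 0.063 after median scaling) and was highest in pigmented 2 at 3.44.

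**Figure D3:**
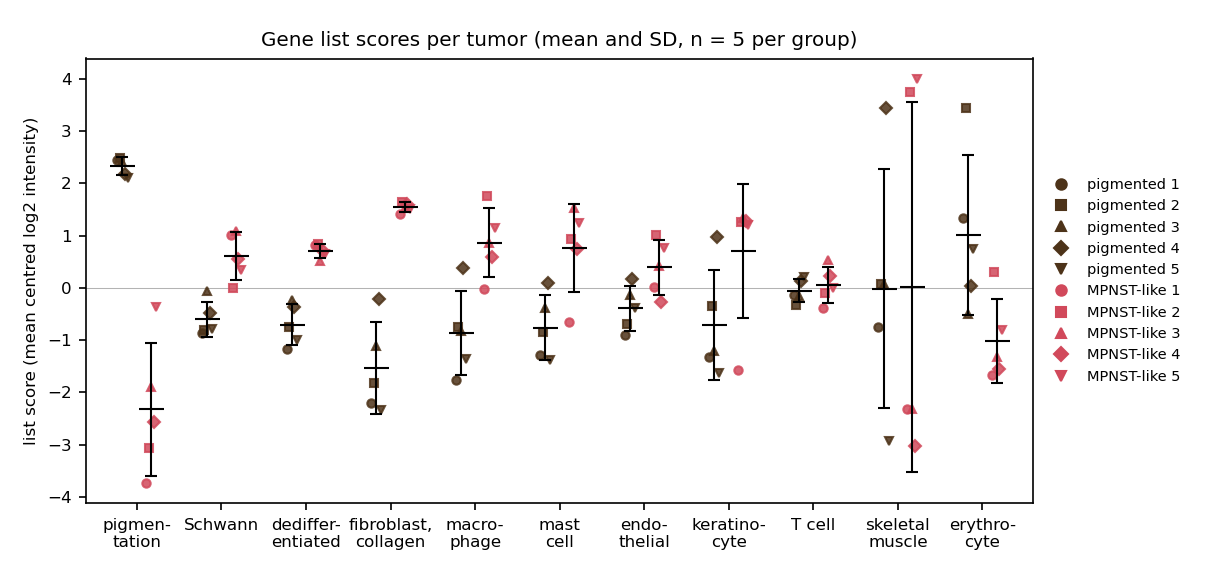
Gene list scores (mean centred log2 intensity, vertical axis) for 11 lists, with 1 point per tumor and bars for the mean and SD of 5 tumors per group. The fibroblast score lies between 1.40 and 1.65 in MPNST-like tumors, and the keratinocyte score of MPNST-like 1 lies at -1.57.

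Genes of energy metabolism were lower. Of 15 oxidative phosphorylation genes 11 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0078, adjusted p = 0.27 with an estimated correlation). The regulator of mitochondrial biogenesis Ppargc1a fell by 2.23, the respiratory chain gene Uqcrc1 fell by 1.05, and Cox7b rose by 1.32. The score differed by -0.54 (exact p = 0.0079), by -0.53 within chip 1 and by -0.54 within chip 2, and by -0.24 (exact p = 0.079) after median scaling and -1.23 in the authors' values. Hypoxia and glycolysis genes fell in 6 of 15 cases and rose in 2 (7 and 2 adjusted over the list alone; camera adjusted p = 0.044, adjusted p = 0.58 with an estimated correlation). The glycolytic enzyme genes Aldoa and Tpi1 fell by 1.89 and 1.77, and Ndrg1 rose by 1.89. The hypoxia score differed by -0.55 (exact p = 0.024), by -0.75 within chip 1 and by -0.41 within chip 2, but by -0.16 (exact p = 0.70) after median scaling and -0.96 in the authors' values. Without pigmented 2, whose score was 1.21 against -0.09 to 0.20 in the other pigmented tumors, it was -0.31 (exact p = 0.040). The hypoxia call was lost in 12 of 27 alternatives, among them without pigmented 2 (adjusted p = 0.15), MPNST-like 4 (0.059) or MPNST-like 5 (0.061). With the keratinocyte score as a covariate its adjusted p was 0.061, while 99.1% of the score difference was left. Cdk4, which carries the R24C allele in this model, was at -0.75 (SE 0.24, adjusted p = 0.029), but the adjusted p was 0.052 to 0.072 when pigmented 1, 3 or 5 or MPNST-like 2, 3 or 5 was left out. The Cdk4 call was lost in 11 of 25 alternatives, over which its log2 difference ran from -1.34 to -0.32 (adjusted p up to 0.59). The 2 Braf probes were detected on 0 arrays, so Braf was not measured. The labels do not say that the tumors came from separate animals, so every p measures only the spread between these samples.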

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

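The tests of the macrophage and mast cell genes, of gene density on chromosome 14, of gene density between chromosomes and of the span of the density fits were chosen after the result was seen. A value is given here when it lay far from the other 4 tumors of its group by Dixon's test. Of 326 groups of values looked at, 26 held such a value, where 16.3 would be expected if every group were normally distributed. Values near background need not be, and genes vary together, so these numbers do not show an excess.

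MPNST-like 5 had more pigment cell RNA than the other MPNST-like tumors, in log2 intensity: Tyr was 6.44 (others 4.15 to 4.31), Mitf 5.18 (4.34 to 4.49), Tspan10 7.23 (4.26 to 4.87), Slc6a17 6.63 (4.40 to 4.68) and Gpr143 5.27 (4.24 to 4.34). Ppargc1a was also high there at 6.07. Its hair follicle score was 1.57, against 1.41 in MPNST-like 3 and -1.47 to -0.98 in the other MPNST-like tumors. The source of its pigment cell RNA was not tested. In MPNST-like 1, Klrd1 (4.95) and Col17a1 (6.16) were low, Tgfbi was high (13.3), and the keratinocyte score of -1.57 lay below the others (1.20 to 1.35). In MPNST-like 2, Egr2 was low (7.53) and Alas2 high (7.89). In MPNST-like 3, Actg2 (9.15) and Atp5a1 (8.91) were low, and in MPNST-like 4 Egfr was low (7.49). In pigmented 1, Tyr was high (9.40). In pigmented 2, Pmel (13.8), Tspan10 (11.0) and Foxp3 (8.42) were low, and the hypoxia and glycolysis score was high at 1.21 (others -0.09 to 0.20). In pigmented 3, Gap43 (7.24, others 4.22 to 4.66) and the neuronal score (-0.29) were high. Clec9a was only slightly above the other pigmented tumors there (4.42, others 4.26 to 4.30). In pigmented 4, Klrd1 (4.90), Ivl (7.42) and Myh4 (8.48) were high.

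The first pattern is the rise of macrophage and mast cell genes in MPNST-like tumors. A lower share of tumor cells would raise vessel and immune genes alike. The macrophage score rose beyond the endothelial score by 0.95 (exact p = 0.016), but its rise of 1.73 was smaller than the 3.08 of the fibroblast score. The endothelial difference was itself 0.36 (exact p = 0.27) in the authors' values. The outcome thus depends on the list taken as reference and does not decide on the share of tumor cells. With the keratinocyte score in the fit the macrophage difference kept 1.004 of its 1.73 (permutation p = 0.024). The macrophage score was -0.03 in MPNST-like 1 and 0.38 in pigmented 4, whose keratinocyte scores (-1.57 and 0.98) were unlike those of their groups. It thus separated the tumors by the sign of the keratinocyte score and not by group. MPNST-like 1 was still the highest of the tumors with a keratinocyte score under 0, and pigmented 4 the lowest of the rest. What the fit leaves rests on these tumors, so it does not decide on skin as the whole cause. The mast cell score rose beyond the endothelial score by 0.74 (exact p = 0.095), which also leaves a lower share of tumor cells open. With the keratinocyte score in the fit the mast cell difference dropped from 1.52 to 0.73, 48.1% of its size (permutation p = 0.048), which is consistent with skin in the specimens as a source of part of it. The phenotype itself, and more immune cells in or around these tumors, stay open and untested.

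The second pattern is pigmented 2, which lay at -53.1 on the third principal component (8.64% of the variance) and had 433 genes more than 1 log2 unit outside the range of the other pigmented tumors, where pigmented 4 had 453 and MPNST-like 1 had 413 against their own groups. Its deviations had a correlation across genes of 0.0103 with gene length (largest size in another tumor 0.0578), which argues against a length trend. Their correlation with gene density within chromosomes was -0.119. Pigmented 5 reached 0.124, but its deviations are taken from a mean that holds pigmented 2. A density trend thus cannot be told apart from other differences of pigmented 2 by that size, and genes are not independent replicates. Its chromosome medians lay outside the range of random gene lists of like expression on 15 of 20 chromosomes. They ran from 0.41 on chromosome 14, 0.29 on 13 and 0.28 on 12 to -0.15 on 11. Over 19 autosomes their correlation with gene density was -0.64. It was 0.74 in pigmented 5, 0.65 in pigmented 3, 0.61 in pigmented 1 and 0.06 in pigmented 4. Each deviation is taken from the mean of the other tumors of the group, so a trend in pigmented 2 enters those tumors with the opposite sign. Their correlations therefore do not show whether the trend is particular to pigmented 2. For the 419 genes of chromosome 14, 0.40 remained after a fit on neighbouring genes. That fit spanned 0.24 over genes, less than the shift of 0.41, so it could have removed only part of it. The chromosome lay 0.34 above the line of the other autosomes on their gene density (largest distance of another autosome 0.22). That distance argues against density between chromosomes as the whole cause of the shift. The broad shifts have no tested cause, and RNA quality, other cells in the specimen and DNA copies stay open.

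The third pattern is chromosome 6 in MPNST-like 1, where the median of 614 genes lay 0.16 above the mean of the other MPNST-like tumors, the only chromosome of this tumor outside the random range. It lay 0.174 above the line of the other autosomes on their gene density (largest distance of another autosome 0.055). The other autosomes thus showed no straight density trend that would carry this shift, which argues against such a trend as its cause. A fit on neighbouring genes left 0.156 but spanned only 0.068 over genes, too little to lower the shift by much, so it decides nothing. An extra chromosome copy in some of the cells is a candidate explanation and remains an untested hypothesis, since DNA was not analysed here and 200 pairs of tumor and chromosome were looked at. On the same chromosome pigmented 2 had a larger shift (0.19), MPNST-like 4 a smaller one (0.11), and MPNST-like 5 (-0.13) and pigmented 1 (-0.10) had shifts of opposite sign. A shift in 1 tumor enters the other tumors of its group with the opposite sign, so these values are not independent.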

How the results depend on the processing

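The fits without the tumors with muscle RNA and with the keratinocyte score were chosen after the data were seen. Signal over background limits genes near the detection floor, and the cause of the changes below was not tested unless named. Genes higher and lower numbered 3845 and 902 with median scaling and 1220 and 3820 with the authors' values. These 2 scalings also moved the median of all genes, to 0.33 and -0.22. Fewer arrays (within chip 1) left 255 and 135. Stricter thresholds by construction left 1267 and 1054 at a log2 value of at least 1, and 1274 and 1514 at an adjusted p under 0.01. With the keratinocyte score as a covariate 1494 genes were lower. Lists higher numbered 6 with that covariate, and lists higher and lower were 0 and 0 with an estimated correlation. Leaving out each tumor in turn gave 1841 to 2375 genes higher, 2018 to 2620 lower, 10 to 14 lists higher and 3 to 5 lower. The other alternatives gave counts within 1.5 times those reported.

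For the 124 named genes, 2683 of 3095 values kept their side of the threshold and direction over all alternatives, 370 lost the call, 8 gained one and 32 moved. For set tests these were 820, 47, 38 and 37, and for list scores, outside the fits within 1 chip, 612, 55, 9 and 22. Within 1 chip the exact p of a list score cannot pass, so these values say nothing about the threshold, and 63 kept their direction within 1 SD and 7 moved. Of all called genes, 118 had the other sign with the authors' values, 90 with median scaling, 13 with the mean of probes, and 1 each with cyclic loess and without background correction. Among values of named genes and list scores that had passed, the sign turned for 2 values of single genes and 1 list score: Cd8b1 was 0.030 (adjusted p = 0.89) with the mean of its probes, and Rpl32 was -0.26 (adjusted p = 0.27) with the authors' values. The ribosomal protein score was -0.52 (exact p = 0.016) with the authors' values. Among values that had not passed, the sign turned for 32 values of named genes, S100b and Kit among them, and for 26 list scores, and the skeletal muscle list turned lower by camera (adjusted p = 0.0095) without the tumors with muscle RNA, which were removed for those genes.

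Mcpt4 lost its call in 16 of 25 alternatives, among them without pigmented 1, 2 or 5 or MPNST-like 2, 3, 4 or 5 (adjusted p = 0.064 to 0.11). The exact p of the MHC class II score was 0.056 to 0.063 without pigmented 1, 2 or 5 or MPNST-like 3, 4 or 5. That of the endothelial score was 0.056 to 0.087 when any tumor but pigmented 4, MPNST-like 1 or MPNST-like 4 was left out. That of the erythrocyte score was 0.056 without MPNST-like 1, 3, 4 or 5. That of the hypoxia score was 0.056 to 0.063 without the same tumors, and that of the immune checkpoint score was 0.056 to 0.063 without pigmented 1 or MPNST-like 3 or 5. Calls by camera were gained without MPNST-like 1 for neutrophil (adjusted p = 0.047) and MHC class I genes (0.040), without MPNST-like 2 (0.018) or pigmented 3 (0.036) for erythrocyte genes, and without pigmented 3 (0.038), 4 (0.014), 5 (0.047) or MPNST-like 4 (0.046) for receptor tyrosine kinases. The ribosomal list was gained without pigmented 4 (0.045) or 5 (0.039). The cytotoxic score reached an exact p of 0.016 without MPNST-like 1 and 0.032 without pigmented 4.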

Other observations

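The fit without the tumors with muscle RNA was chosen after the result was seen. Several signalling and growth lists were not called as groups. Of 15 MAPK output genes 3 were higher and 4 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.50; score difference -0.24, exact p = 0.25, but -0.70 with exact p = 0.0079 in the authors' values and 0.10 after median scaling). The feedback phosphatase gene Dusp4 fell by 2.57, Etv5 by 1.98 and Phlda1 by 1.77, whereas Egr1 rose by 1.98. Of 9 YAP and TEAD targets 5 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.085; score difference 0.98, exact p = 0.0079, and 0.62 in the authors' values), with Ccn1 at 2.25, Ccn2 at 2.10 and Ptpn14 at -1.33. Of 18 receptor tyrosine kinases 8 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.055; score difference 0.74, exact p = 0.024, and 0.49 with exact p = 0.10 in the authors' values), with Pdgfra at 3.23 and Ntrk2 at 2.44. Axl belongs to both of these lists and to the dedifferentiated list. Of 9 MPNST tumor suppressor and PRC2 genes 2 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.80; score difference 0.07, exact p = 0.75, with -0.36 in the authors' values and 0.52 after median scaling). Cdkn2a was at -1.37 and Nf1 at -0.89, Cdkn2b at 1.23 and Rassf1 at 0.97. The Nf1 call was lost in 13 of 25 alternatives, that of Cdkn2b in 10, and those of Cdkn2a and Rassf1 in 4 each. Cell cycle genes were lower in 2 of 22 cases and in 0 adjusted over the list alone (camera adjusted p = 0.50; score difference -0.17, exact p = 0.58, and 0.33 after median scaling), with Mcm5 at -1.11. Immediate early and heat shock genes were higher in 2 of 11 cases, also adjusted over the list alone (camera adjusted p = 0.50; score difference 0.37, exact p = 0.33, and 0.76 with exact p = 0.079 after median scaling), with Jun at 0.70. Ribosomal protein genes were higher in 3 of 10 cases (4 adjusted over the list alone; camera adjusted p = 0.062; score difference 0.36, exact p = 0.0079, but -0.52 with the authors' values), with Rps6 at 1.34.

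Other immune and tissue lists were not called either. Interferon response genes were higher in 3 of 13 cases (2 adjusted over the list alone; camera adjusted p = 0.37; score difference 0.35, exact p = 0.11, and 0.71 with exact p = 0.016 after median scaling), with Oasl2 at 1.96 and Ifit2 at 1.52. Of 13 MHC class I genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.19; score difference 0.41, exact p = 0.27, and 0.81 with exact p = 0.040 after median scaling), and Psmb8 was at 1.13. Of 5 immune checkpoint genes 2 were higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.29; score difference 0.50, exact p = 0.032, 0.25 with exact p = 0.34 in the authors' values and 0.24 without background correction). Cd276 was at 1.96, and Cd274, which encodes PD-L1, fell by 1.84. Neutrophil genes were higher in 2 of 8 cases (1 adjusted over the list alone; camera adjusted p = 0.085; score difference 1.60, exact p = 0.048, 1.29 with exact p = 0.071 in the authors' values and 1.06 without background correction), with Retnlg at 3.81 and the highest score in MPNST-like 2 (3.54). Without MPNST-like 2 the neutrophil difference was 0.91 (exact p = 0.087). Cytotoxic and NK cell genes were higher in 2 of 6 cases (1 adjusted over the list alone; camera adjusted p = 0.19; score difference 0.66, exact p = 0.056, 0.93 with exact p = 0.024 after median scaling and 0.29 without background correction), with Klrd1 at 2.28. Of 5 B and plasma cell genes 1 was higher, also adjusted over the list alone (camera adjusted p = 0.18; score difference 0.38, exact p = 0.016, and 0.13 without background correction), namely Cd79b at 0.94. Of 12 adipocyte genes 1 was lower, also adjusted over the list alone (camera adjusted p = 0.65; score difference 0.42, exact p = 0.52, and 0.03 to 0.78 over 22 alternatives), namely Pparg, which fell by 2.51. Of 11 hair follicle genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.86; score difference -0.33, exact p = 0.82), and the score was highest in pigmented 4 (3.18). Without pigmented 4 the hair follicle difference was 0.43 (exact p = 0.64). The skeletal muscle score differed by 0.04 (camera adjusted p = 0.91) and by -1.67 without the tumors with muscle RNA (exact p = 0.11).

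Of 100 splits drawn of the 10 tumors into 5 and 5, 1, the real one, gave as many genes as the real 4646, and the highest of the others gave 1097. The number of genes was thus beyond that of every other split drawn. With 100 splits no share under 1 in 100 could be reached, and the labels do not say that the tumors came from separate animals. For the lists 22 splits gave at least the real 16, and the highest other gave 24, so chance cannot be excluded for the number of lists. The split with 1097 genes set pigmented 1, 2, 3 and 5 and MPNST-like 1 against the rest and gave 22 lists. It exchanges pigmented 4 and MPNST-like 1, the tumors of each group nearest to the other on the first principal component (-22.1 and 38.8), and the 5 tumors it sets apart are also those with a keratinocyte score under 0. No test here separates the phenotype from the keratinocyte score as the source of the calls in that split. In the real split, with that score as a covariate, 1489 genes were higher and 1494 lower.

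Xist was high in pigmented 1 (9.96), pigmented 3 (9.30), MPNST-like 3 (9.81) and MPNST-like 5 (10.53). The Y-linked gene Eif2s3y was high in MPNST-like 1 (8.65), MPNST-like 2 (9.52), MPNST-like 4 (7.31), pigmented 4 (8.36) and pigmented 5 (8.31). Pigmented 2 was high in neither (Xist 4.25, Eif2s3y 4.57), while Kdm5d was 5.55 there. The Y-linked gene Kdm5d was 5.65 to 6.40 in the tumors high in Eif2s3y and 4.22 to 4.75 in those high in Xist. Uty was 4.96 in pigmented 2, but its ranges overlapped, at 4.63 to 4.87 in the tumors high in Eif2s3y and 4.24 to 4.77 in those high in Xist.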
